A study of Fundulus heteroclitus with 20 samples.

How the data were processed

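The series measured RNA levels in newly hatched killifish (Fundulus heteroclitus, a small estuarine fish used in toxicology) on 20 Agilent arrays with 1 colour, Cy3. Per the labels, fertilized eggs were kept in dishes of 40 in water with 0 or 25 ppm arsenic, given as sodium arsenite, until they hatched, and the fish were taken less than 24 hours after hatching. Each array held RNA pooled from 4 to 5 hatchlings of 1 dish, with 10 dishes per group, so the arrays of a group come from separate dishes. The labels name an RNeasy kit for the extraction and the Quick Amp kit for labelling. Groups and replicate numbers were taken from the sample titles.

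Each array had 1 scanner file, written by Feature Extraction 10.7.3.1 per the file headers. The processed intensity in these deposited files was background-subtracted and detrended within the array per the file headers, with no scaling between arrays. The mean intensity and local background intensity of each spot in the deposited files were raw. Per the file headers, flags in other columns mark control spots, spots well above background, saturated spots and spots that are outliers in uniformity or within their replicates. The authors also deposited a value table holding a log2 value for each probe and array, and its normalization was not given in the sources used here. Set against the scanner files, its rows followed the spot after each named probe's own spots, and 7 of its 20 columns followed the file of another control array. The values lay near the log2 of the linear mean of a probe's spots plus a shift for each array, with column medians between 5.02 and 5.18. Around that shift the SD over probes was 0.24 to 0.42 against the best matching file, so a shift alone did not reproduce them. How the shift was set, and any further step or centring across arrays, stayed unknown. For these reasons the deposited log2 values were used only for a count of probes, with no gene named from them.

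The main values were log2 of the processed intensity, averaged over the spots of a probe, minus the 75th percentile of each array over its non-control probes. Outlier spots were left out, and saturated spots would have been kept, but there were 0. Of 21821 probes, 11759 were well above background on at least 5 of the 10 arrays of at least 1 group and were tested. Tests were fitted with limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8), as arsenic minus control with no covariate, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. A fold is 2 raised to the log2 difference, and errors are SE of the fitted difference unless an SD is named. The precision of each value is limited by the number of arrays.

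Gene names came from the probe descriptions in the scanner files, which give the best protein match of the expressed sequence tag behind the probe. A name was used where the match had an expect value of at most 1e-05 and was informative. This named 1159 probes, or 749 genes, while 605 probes had an uninformative match, 175 a weak match, 14 a vector match and 19868 no match. A gene name therefore stands for similarity to that protein, some names are clipped at 50 characters in the files, and the strand of the tags was not checked. None of the tag identifiers, 0 of 16185, was found in the reference table of gene identifiers, and genome positions were not used here. Each of 511 named genes with a tested probe was represented by its probe with the highest mean level over all 20 arrays. Of these, 66 had more than 1 tested probe, and 14 of the 66 had probes called in both directions.

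Before the data were examined, 34 gene lists, the tests, the main alternatives and the rule for naming genes were fixed. The rule named the 10 genes with the largest rise and the 10 with the largest fall past the threshold and well above background on every array of at least 1 group. It also named up to 4 members of each list that passed the list test, and 13 fixed genes tied to arsenic, muscle or stress, such as metallothionein and heme oxygenase. The list test called no list, and 0 of the fixed genes were tested under a matching name, so both parts gave no gene. The result for 1 of the 10 falls is not reported here. Up to 3 members of each tested list with the smallest p were chosen as examples after their values were seen, as were other members named below. Lists with at least 5 measured members, 13 of the 34, were tested against the other named genes with camera from limma at a preset correlation of 0.01. The same lists were also tested with an estimated correlation and with fry, a rotation test of whether a list moves on balance in 1 direction. The muscle, keratin and collagen lists were chosen knowing that the study's publication dealt with muscle development in these fish.

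Array measures were compared by permutation tests of the group labels with 100000 resamples, two-sided, adjusted over the measures. The arrays lay on 5 slides that each held both groups, and slide was tried as a fixed and as a random block and each slide on its own. The other alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, no filter or a stricter filter on dim probes, outlier spots kept, slide and array position together, the replicate number as a block, array weights, an intensity-dependent variance prior, each slide left out, other thresholds, the mean or the other probes of a gene, a permutation test per gene and the authors' table. The normexp offset is added to every signal before the log2, so it shrinks log2 changes by construction, most in dim probes. Alternatives added after the data were seen were scaling to the spike-in probes, control replicates 4, 6 and 7 and arsenic replicate 1 left out, the 75th percentile as a covariate, the replicate number of the file names as a block, and camera against all probes.

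The procedure was tested on simulated data with the spread of these arrays for 11759 probes and 10 arrays per group. It called 82% of probes changed by 1 on the log2 scale and 31% of those changed by 0.5 in the right direction, and 5.83% of its calls were unchanged probes. The shifted list was called, and 0 of 30 unshifted lists were. The simulation changed few probes, drew the probes independently and moved all members of the shifted list alike. In these arrays many probes changed and lists held members moving both ways, so these rates need not hold here. Other splits of the real arrays called up to 4 lists. Unnamed probes were left out of the gene and list results but kept in the counts of probes.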

Results

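Gene expression was measured in pools of whole killifish hatchlings that had developed in water with 25 ppm arsenic or without added arsenic, on 10 arrays per group. The share of probes well above background was 50.5% ± 1.88 (SD, n = 10) on the arsenic arrays and 49.7% ± 3.02 (SD, n = 10) on the control arrays, and 0 spots were saturated. The design asked how exposure during embryonic development changed the transcripts of the hatched fish. Of 11759 probes tested, 511 genes carried a usable name.

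Among the largest rises in hatchlings from arsenic water were single genes named by similarity to an exporter, a conjugating enzyme and plasma carriers of hormones. The canalicular multispecific organic anion transporter, which moves glutathione conjugates and arsenic-glutathione complexes from liver cells into bile, rose 10.6-fold (log2 change 3.41 ± 0.26 SE, n = 10 per group) by the brighter of its probes, while another did not pass. Omega class glutathione-S-transferase, an enzyme class that can reduce methylated arsenic, rose 9.06-fold (3.18 ± 0.35). Corticosteroid-binding globulin rose 7.02-fold (2.81 ± 0.34) and thyroxine-binding globulin 4.69-fold (2.23 ± 0.35). In the opposite direction, Actin 1, at −2.002 on the log2 scale, fell 4.004-fold and the mitochondrial cytochrome b transcript fell 2.39-fold.

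The 10 largest rises had adjusted p-values (limma) between 1.91e-08 and 2.54e-05, and in each of them 10 of 10 arsenic arrays lay above the control mean. They included the epsilon subunit of the nicotinic acetylcholine receptor, part of the receptor at mature nerve-muscle junctions. Its probe was well above background on 10 arsenic arrays but on 1 control array, so the size of its rise is uncertain. It was 2.65 on the log2 scale in the main values and 0.30 after normexp correction, whose offset shrinks changes of dim probes. The muscle type of 6-phosphofructokinase, which catalyses a controlling step of glycolysis, rose 4.51-fold. Stromal cell derived factor receptor 2 rose 5.67-fold, and chimera galectin Gal3, a lectin that binds galactosides, rose 4.31-fold. Cytochrome P450 2J2, an epoxygenase of fatty acids, rose 4.75-fold and transmembrane 4 superfamily member 4 rose 5.09-fold, with control probes well above background on 7 and 4 arrays. The probes of a gene did not always move together: the second transporter probe changed by 0.19 ± 0.16 and did not pass the test, whereas the second thyroxine-binding globulin probe rose by 2.08 ± 0.31. Each of the 10 rises kept its direction and its call under quantile normalization and normexp (median and spike-in scaling shift all changes upwards by a constant). All 10 were smaller with normexp, but its offset shrinks changes by construction, so the smaller sizes are no evidence of smaller effects. The log2 change became 2.17 for the transporter, 2.66 for the transferase, 1.47 for corticosteroid-binding globulin and 1.70 for stromal cell derived factor receptor 2. It was 1.54 for thyroxine-binding globulin and 1.43 for 6-phosphofructokinase. For transmembrane 4 superfamily member 4 it was 0.33 and for cytochrome P450 2J2 0.45. Control signal of these last genes was not always well above background, so their sizes are uncertain too.

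Among the 10 largest falls, Actin 1 changed by −2.002 ± 0.19 on the log2 scale and 60S ribosomal protein L18a by −1.69 ± 0.23, both kept as falls under spike-in scaling at −0.74 and −0.44. Mitochondrial oligoribonuclease, which degrades very short RNA, changed by −1.67 ± 0.33, the beta subunit of T-complex protein 1 by −1.47 ± 0.22 and cytochrome b by −1.26 ± 0.17. Spike-in scaling ended the call of these last genes, leaving −0.41, −0.21 and −0.00245. Hemoglobin beta chain (−1.25 ± 0.19), a retrovirus-related POL polyprotein (−1.22 ± 0.14), the F-box protein Fbxw9 (−1.21 ± 0.20) and kinesin family member 21B (−1.18 ± 0.22) also fell, but turned to between 0.0076 and 0.074 under spike-in scaling, with no call. Under normexp these falls kept their call but were smaller, with −0.68 for Actin 1, −0.49 for T-complex protein 1 beta, −0.13 for oligoribonuclease, −0.12 for L18a and −0.084 for hemoglobin beta chain. The normexp offset shrinks changes of dim probes by construction, so these sizes cannot show that the falls are small. A second POL probe rose by 2.86, and the second probe of T-complex protein 1 beta changed by −0.15 ± 0.27. Within slide 2 the kinesin was higher with arsenic, by 0.54. Well above background on the arsenic arrays were 6 for L18a, 5 for oligoribonuclease and 8 for hemoglobin beta chain.

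**Figure D1:**
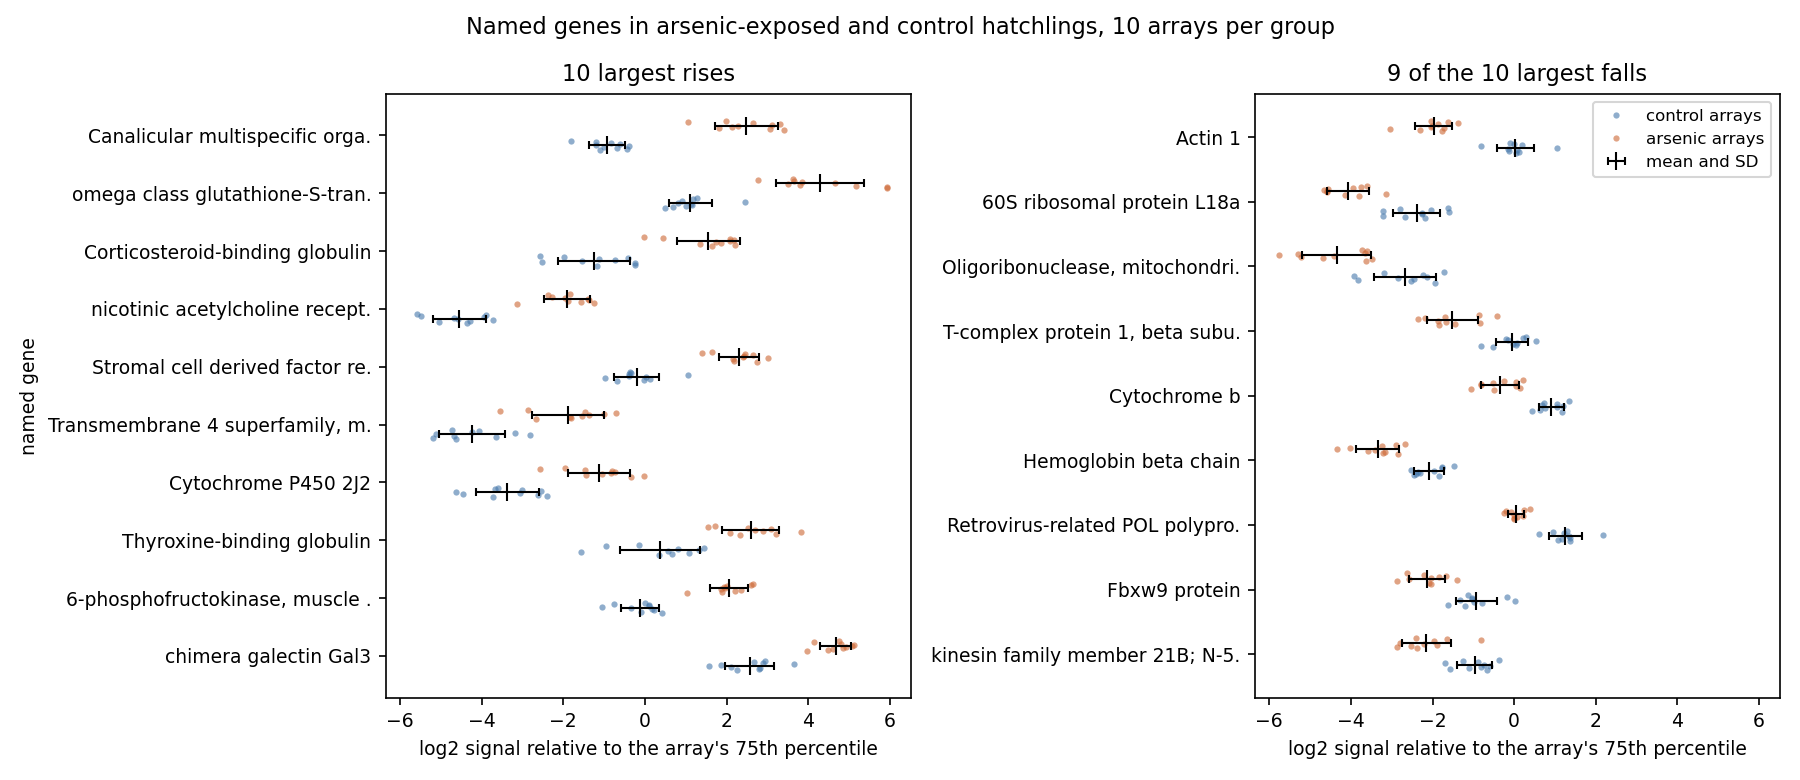
Log2 signal relative to the 75th percentile of each array (x axis) for the 10 named genes with the largest rise (left) and 9 of the 10 with the largest fall (right), with a point per array, 10 control and 10 arsenic, and black marks for mean and SD. The transporter's mean was 2.48 on arsenic arrays against −0.93 on control arrays, and Actin 1 had −1.98 against 0.026, while 4 of these falls turned slightly positive under spike-in scaling.

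In the list for enzymes of foreign compounds, more genes were called higher than lower. Of 9 measured genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median change of 0.88 (camera, adjusted p = 0.292, and unadjusted p = 0.0272). The list was drawn by name. It also held betaine aldehyde dehydrogenase (0.72, counted among the rises) and cytochrome P450 24A1, which are not chiefly enzymes of foreign compounds. Besides cytochrome P450 2J2, SULT1 sulfotransferase isoform 2 rose by 1.61 ± 0.26 and UDP-glucuronosyltransferase 2B20 by 1.05 ± 0.21, which attach sulfate and glucuronic acid to their substrates. Under normexp these changes were 0.29 and 0.27, and the list median was 0.29 with 7 rises. Cytochrome P450 24A1 (−0.19) and 4B1 (0.14) did not pass.

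Of 10 glycolytic genes measured, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with a median of 1.28 (camera, adjusted p = 0.292), or 0.42 under normexp and 2.54 under spike-in scaling. Phosphoglycerate mutase 2, the muscle form, rose by 1.84 ± 0.13, gamma enolase by 1.85 ± 0.17, the muscle pyruvate kinase by 1.30 and aldolase B, the liver form, by 1.26. Alpha enolase (−0.67) and aldolase A (−0.34) fell, while under quantile, median and normexp scaling 0 members of the list fell and under spike-in scaling both rose. Of 18 measured genes in the oxidative phosphorylation list, 10 fell and 4 rose (10 and 4 adjusted over the list alone), with a median of −0.40 (camera, adjusted p = 0.292). Cytochrome b, among the largest falls above, was not in this list. The falls included transcripts of the mitochondrial genome, such as cytochrome c oxidase polypeptide II (−0.62 ± 0.12) and NADH-ubiquinone oxidoreductase chain 2 (−0.63). Under quantile normalization the fall of polypeptide II was smaller, at −0.225. Rises included a core protein of ubiquinol-cytochrome c reductase (1.01 ± 0.16, or 0.32 under normexp). The count of falls depended on the scaling: it was 6 under quantile normalization, 7 under normexp and 0 under median scaling, and under spike-in scaling all 18 rose. So did the list median, at −0.036 under quantile normalization, −0.026 under normexp, −0.00077 under median scaling and 0.86 under spike-in scaling.

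Genes of protein synthesis, folding and breakdown moved in different ways. Of 5 proteasome genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.71 (camera, adjusted p = 0.292). The non-ATPase regulatory subunits 13 and 4 rose by 1.42 ± 0.23 and 0.71 ± 0.14. Among heat shock proteins and chaperones, 3 of 6 rose and 3 fell (3 and 3 adjusted over the list alone), and their median of 0.21 and mean of 0.12 were above 0 while camera ranked the list downwards (adjusted p = 0.931). Subunits of the same cytosolic chaperonin moved apart, since subunit 6A rose by 1.33 ± 0.14, epsilon by 1.15 ± 0.15 and alpha by 0.89 ± 0.12, whereas beta (−1.47) and theta (−0.48) fell, with no call for beta and a rise of theta to 0.77 under spike-in scaling. Heat shock 27 kDa protein fell by 0.70 but rose to 0.55 under spike-in scaling. Translation factors had 5 rises and 3 falls of 10 (5 and 3 adjusted over the list alone, camera, adjusted p = 0.589), from elongation factor 1-alpha at 1.09 ± 0.15 to polyadenylate-binding protein 1 at −0.996 ± 0.13, the latter turned to 0.26 by spike-in scaling. Ribosomal proteins had 6 rises, 6 falls and 19 without a call among 31 (6 and 6 adjusted over the list alone, camera, adjusted p = 0.318). Their median was −0.11 and their mean 0.019, and the balance depended on the scaling: 7 rose and 7 fell under quantile normalization (median 0.098), 11 and 5 under normexp (0.018), 19 and 1 under median scaling (0.29) and 29 and 1 under spike-in scaling (1.15).

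Transcripts typical of liver and pancreas were more often called higher than lower. Of 10 plasma proteins and other liver products, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.54 (camera, adjusted p = 0.318), or 5 and 0 under quantile normalization. With the mean of each gene's probes, camera ranked the liver list downwards (adjusted p = 0.952). The list mean was −0.069 within slide 2. Liver fatty acid-binding protein, counted among the rises at 0.76, had another probe called lower, at −1.72. Apolipoprotein A-I rose by 1.29 ± 0.25, although another of its probes fell slightly at −0.12 with no call, and apolipoprotein E rose by 1.02 ± 0.22 with −0.073 within slide 2. Serotransferrin I fell by 0.48, a fall that quantile, median and normexp scaling ended and spike-in scaling turned to 0.78. Of 6 exocrine pancreas genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.89 (camera, adjusted p = 0.318), but 2 rose under quantile normalization and 3 under normexp, and the list mean was −0.33 within slide 4. Chymotrypsin A rose by 1.28 ± 0.33, and trypsin I, at 1.38 ± 0.50, lost its call in 7 alternatives, such as slide as a fixed block (0.88). The rises counted for pancreas include an alpha-1-antitrypsin homolog (0.36), a plasma protein that is also counted in the liver list. In the complement and immune list, 3 of 7 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of 0.29 (camera, adjusted p = 0.589). The rises were complement factor B (1.66 ± 0.27), C3-1 (1.26 ± 0.15) and factor H (1.18 ± 0.18), or 0.99, 0.44 and 0.68 under normexp, the last pair with other probes at −0.35, with no call, and −0.53, a called fall, and the falls were 2 immunoglobulin genes that rose under spike-in scaling, while under quantile, median and normexp scaling 1 member of the list fell. In the lipid list, 3 of 6 rose and 2 fell (3 and 2 adjusted over the list alone, camera, adjusted p = 0.931), among them long-chain acyl-CoA dehydrogenase at 1.198 ± 0.18, with another probe at −0.013, and acetyl-CoA carboxylase 1 at −0.83, or 0.43 with no call under spike-in scaling.

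Keratin genes had 4 rises and 1 fall among 6 (4 and 1 adjusted over the list alone), with a median of 0.66 (camera, adjusted p = 0.447) and keratin 18 at 1.22 ± 0.15. Contractile genes of the sarcomere had 7 rises and 1 fall among 13 (7 and 1 adjusted over the list alone), with a median of 0.49 (camera, adjusted p = 0.646), or 0.076 under normexp. With the mean of each gene's probes, the list median lay at −0.11 against all named genes. Myozenin 2 rose by 1.80 ± 0.35 and myomesin 1 by 1.001 ± 0.25 (0.59 and 0.26 under normexp), while embryonic fast skeletal myosin heavy chain (−0.18) and skeletal alpha actin (0.27) did not pass. Because these lists were drawn up knowing of the study's muscle publication, their counts are not independent evidence of direction. The single fall in each, type I cytokeratin (−0.40) and myosin light polypeptide 4 (−0.42), was not called under median scaling and turned to a rise under spike-in scaling, and that of the myosin was not called under quantile or normexp scaling either.

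**Figure D2:**
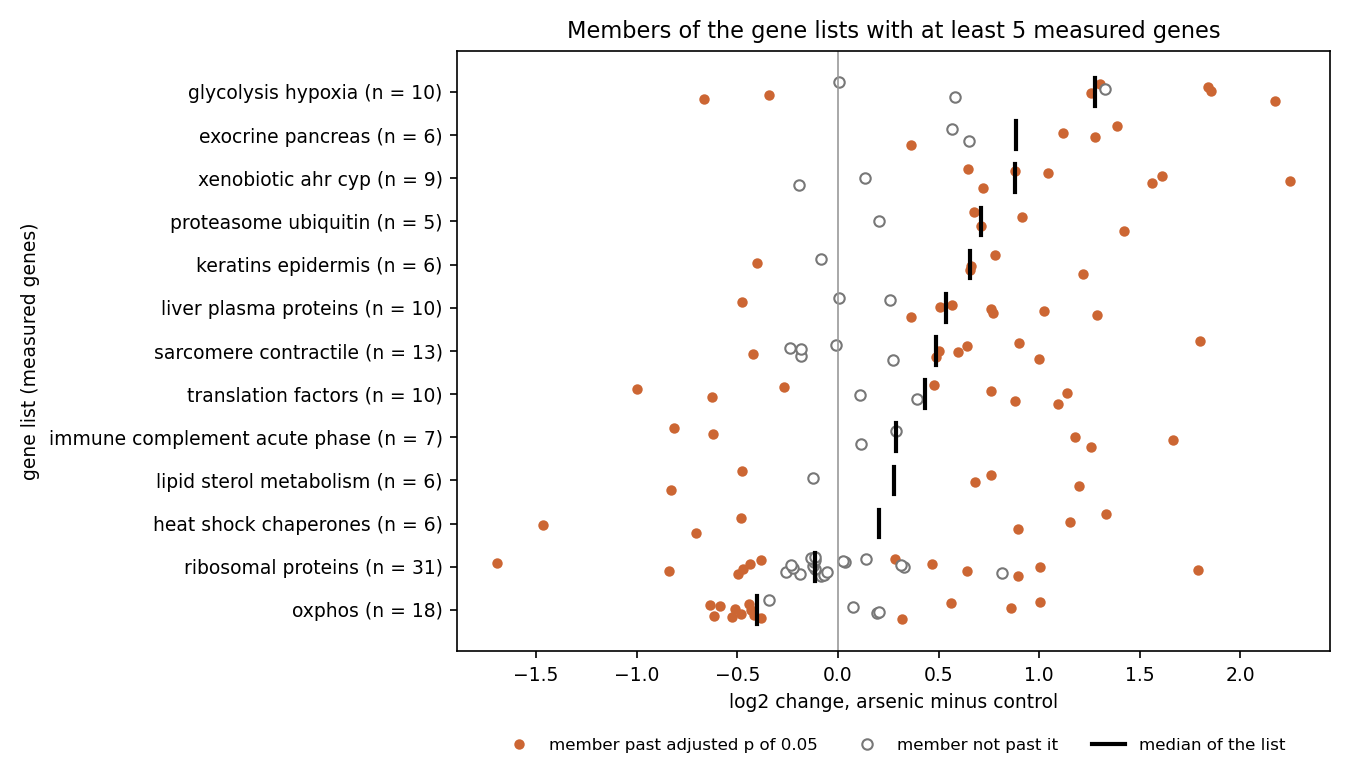
Log2 change with arsenic (x axis) of each measured member of the 13 lists with at least 5 members (y axis), with filled points for members past the threshold, open points for the rest and a black bar at the list median. Medians run from −0.40 for oxidative phosphorylation to 1.28 for glycolysis and hypoxia. The lower medians, of oxidative phosphorylation and ribosomal proteins, turn positive under spike-in scaling.

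No list differed from the other named genes by camera after adjustment. The count was 0 of 13, with 1 list at an unadjusted p under 0.05, and with an estimated correlation the smallest adjusted p was 0.776. By fry, which asks only whether a list moves on balance 1 way, 11 lists passed, all but ribosomal proteins (adjusted p = 0.515) and oxidative phosphorylation (adjusted p = 0.0883). Named genes as a whole leaned upwards, since 313 of 511 changed, 188 higher and 125 lower, with a median change of 0.14. Each list mean was higher within all 5 slides for glycolysis with hypoxia, foreign-compound metabolism, proteasome, keratins, translation factors and the complement list. The other list means were of mixed sign.

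Over all probes, 7304 of 11759 changed, 2655 higher and 4649 lower with arsenic, so 36.3% of the changed probes were higher. This split was set by the scaling. The calls were 2667 higher and 3317 lower under quantile normalization, 4598 higher and 1420 lower under median scaling, and 10517 higher and 82 lower under spike-in scaling, with 76.4% and 99.2% higher in the last pair. The median probe shifted by −0.21 with 75th percentile scaling, −0.062 with quantile normalization, 0.19 with median scaling, −0.01 with normexp and 1.05 with spike-in scaling, and log2 changes given here are relative to these baselines. Between main and quantile calls, 2305 probes were higher in both, 3019 lower in both and 0 opposite, whereas spike-in scaling turned 3563 calls to the opposite direction. With the 75th percentile as a covariate 3801 probes changed. With slide as a block 6734 probes changed. Of the probes called without a given slide, between 91.1% and 97.7% had the same sign within that slide, against 79.9% to 85.9% of all probes (chosen after the data were seen).

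With 75th percentile scaling, dim and bright probes differed in direction. With the probes split into 3 equal parts by mean level, 305 rose and 2137 fell among the dimmest and 1312 rose and 995 fell among the brightest. Quantile normalization, which gives all arrays the same distribution and so removes such a difference by construction, left 600 rises and 744 falls among the dimmest and 1032 rises and 1203 falls among the brightest.

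The arrays themselves differed between the groups. The 75th percentile of log2 signal was 6.99 ± 0.24 (SD, n = 10) on arsenic arrays and 6.43 ± 0.34 (SD, n = 10) on control arrays, a difference of 0.56 (permutation test, adjusted p = 0.0004) and of 0.61 with slide as a block. Within slides 1 to 5 the difference was 0.64, 0.66, 0.75, 0.32 and 0.64. The spike-in probes, which report control RNAs added to each sample, went the other way: their mean was 9.85 ± 0.39 on arsenic arrays and 10.55 ± 0.31 on control arrays, a difference of −0.70 (permutation test, adjusted p = 0.00142, chosen after the data were seen). The slope of spike-in signal on spike-in amount, as the scanner software reports it, was 0.89 with arsenic and 0.73 in controls (adjusted p = 0.00025), with a slope of 0 reported for control replicate 6 and a control mean of 0.82 without it. The share of probes well above background (adjusted p = 0.613) and the count of outlier spots, 18.4 against 10.8 (adjusted p = 0.613), did not pass, and without arsenic replicate 1 the arsenic mean of outlier spots was 11.4.

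**Figure D3:**
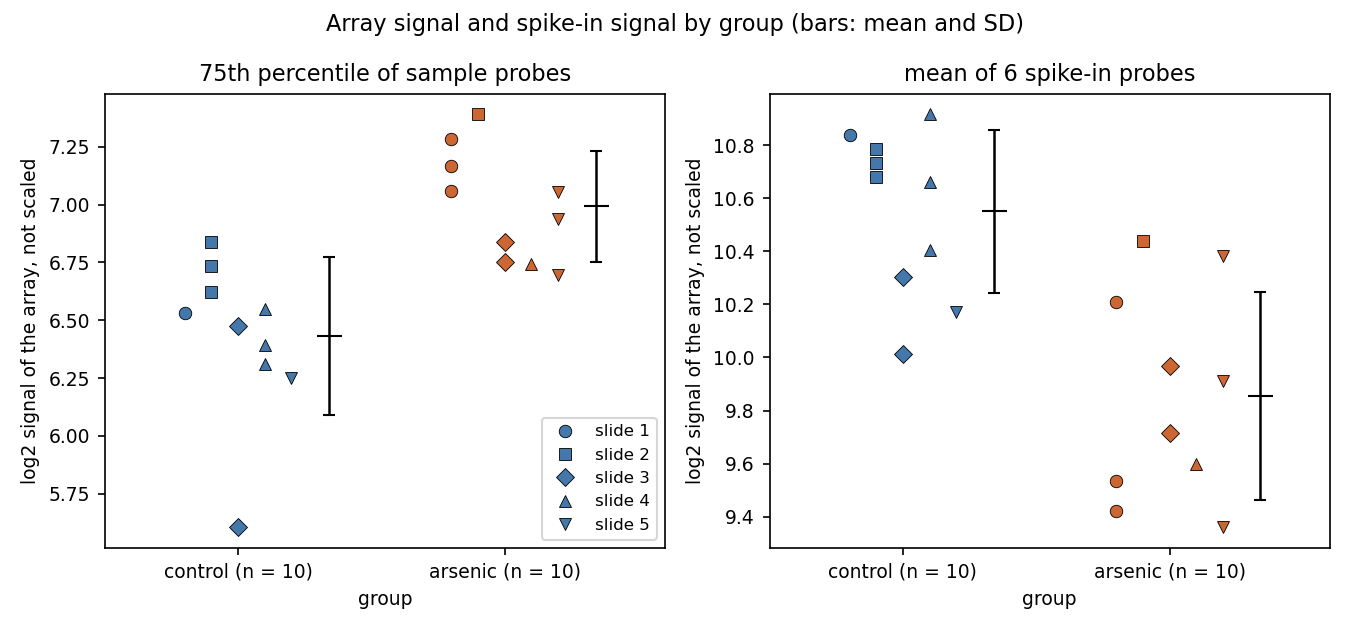
Log2 signal of each array before scaling (y axis) for the 75th percentile of sample probes (left) and the mean of 6 spike-in probes (right), by group (x axis), with marker shapes for the 5 slides and bars for mean and SD, 10 arrays per group. Sample signal was higher with arsenic by 0.56, and the spike-in signal differed by −0.70.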

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

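The tests of spike-in signal, slides, RNA ratio, its part in the gap, liver share and table rows, and the runs without single arrays, were chosen after their results were seen; the tests of background in dim probes and of other splits were chosen before.

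The arsenic arrays gave more sample signal, yet dim probes fell behind bright ones with 75th percentile scaling. A brighter scan or hybridisation as the only cause is argued against by the spike-in probes, which differed by −0.70 between arsenic and control. Together with a lower share of spike-in in the arsenic samples, a brighter scan is not excluded. The slides are argued against by a higher 75th percentile with arsenic in 5 of 5 slides. Additive background that holds dim probes back would need a slope of −0.83 of the gap between dim and bright probes on array signal, and within groups the slope was −0.0700 (95% interval −0.30 to 0.16), or −0.057 without control replicate 6. A higher ratio of sample RNA to spike-in before hybridisation, which may come from handling or from the fish, stays open: the 75th percentile less the spike-in mean differed by 1.26, and since the amounts used in labelling are not given in the sources used here, handling and treatment cannot be told apart. Such a ratio would raise dim and bright probes alike, so as the whole cause of the gap between them it is argued against by a gap that differed by −0.46 between arsenic and control (95% interval −0.59 to −0.34), and with spike-in scaling the median change was 0.83 in the dimmest and 1.35 in the brightest of 3 equal parts. The slope of spike-in signal on spike-in amount also differed, at 0.89 with arsenic and 0.82 in controls without replicate 6. Spike-in probes with a mean log2 signal of at most 5 were left out of the spike-in mean. They differed by between −1.80 and 0.36, whereas the 6 probes used differed by between −0.78 and −0.60. Whether the slope has a part in the gap was not tested. An effect of arsenic on the fish stays among the open explanations, untested.

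Large rises of liver-made genes form another pattern, with the canalicular transporter, corticosteroid-binding globulin and thyroxine-binding globulin as examples. A larger share of liver in the arsenic hatchlings would raise the liver plasma protein list by about as much as these genes, but its median change was 0.54 with an SD of 0.51 over 10 members, against 2.23 for the smallest of the large rises. With these 3 genes added to the list the median was 0.76 (SD 1.13, 13 genes). The list thus rose by less than these 3 genes, but they were picked for their large rises, so such an excess was likely in advance. The comparison therefore cannot decide how far liver share explains the large rises. A rise in liver share and a response of liver cells to arsenic both stay open as hypotheses. The second probe of the transporter changed by only 0.19, so its size also rests on 1 probe.

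The row names of the authors' value table did not follow the scanner files. Rows of the table correlated with the spots that follow each probe's own spots at r = 0.999 across probes, and with the probe's own spots at −0.0073. Displaced probe names in the scanner files are argued against by 379 probe pairs that share 30 bases, whose mean levels correlated at 0.768 in the scanner files and at 0.014 in the table. A displacement of the table's rows by 1 spot may therefore explain the mismatch, and no biological explanation was tested.

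A chance division of the arrays is argued against for the count of changed probes. Of 100 splits of the 20 arrays into 10 and 10, 1, the real one, gave as many as 7304, and the highest of the others gave 4. The splits did not keep the slides. They cannot tell arsenic from another difference between the groups, such as array signal. For the list test the real value was 0 lists, so all 100 splits gave as many whatever the data (the highest of the others gave 4), and the comparison decides nothing.

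Single arrays stood apart from the rest of their group in 15 of 144 groups of values tested, where chance alone gives about 1 in 20, or 7.2. Control replicate 6 had the lowest 75th percentile, 5.61, and a spike-in slope of 0. Without it 7132 probes changed. Outlier spots numbered 81 on arsenic replicate 1 and 23 on control replicate 4. Control replicate 4 was lowest in liver fatty acid-binding protein (6.58), in the mean of the liver list (2.91) and in that of the complement list (−0.63), and without it 7177 probes changed and the protein rose by 0.60. Control replicate 7 was lowest in trypsin I (0.21) and in the pancreas list mean (2.04) and highest in omega class glutathione-S-transferase (2.45), and without it 7431 probes changed and trypsin I rose by 0.98, still past the threshold. Arsenic replicate 1 was lowest in muscle 6-phosphofructokinase (1.02) and in the keratin list mean (3.54). The remaining values were myomesin 1 at −0.41 on arsenic replicate 5, myozenin 2 at 1.71 on arsenic replicate 3 and the POL polyprotein at 2.18 on control replicate 6.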

How the results depend on the processing

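Spike-in scaling, the 75th percentile as a covariate, camera against all probes, the block by file number, the shares by signal level and the runs without single replicates were chosen after the data were seen. Main counts were 7304 probes changed, 2655 higher and 4649 lower, 19 named genes and 0 lists. The probe count moved to 13807 (11139 lower) with no filter, where more probes were tested, to 3801 (1579 higher, 2222 lower) with the covariate and to 4367 (2506 lower) at 1.5-fold or more. Median scaling gave 4598 higher and 1420 lower, normexp 3017 lower, spike-in scaling 10517 higher and 82 lower, and the values deposited by the authors 2321 lower. The deposited values gave 4905 probes changed. The filter on dim probes was applied there by row names that the values do not follow, so this count is not for the same probes. The other alternatives stayed within 1.5 times, from 5808 to 8074 probes changed. Without single replicates (control 4, 6, 7 or arsenic 1) the count was 7132 to 7431, with 2595 to 2758 higher and 4505 to 4673 lower. Of the 19 named genes, 12 kept their call under spike-in scaling, 18 with the covariate and 13 with the stricter filter, which tested fewer genes; all 19 did elsewhere, but other probes had no call for the transporter (0.19) and T-complex protein 1 beta (−0.15) and the opposite one for POL. List calls were 11 by fry and 5 by camera against all probes; other settings gave 0. The table could not be used for lists or named genes, since its rows carry other names. Slide as a random block had a correlation of 0.038.

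The replicate block used 7 shared numbers of the sample titles, and 6270 probes changed. File names carry another number than the title for 4 arrays; by them 9 numbers were shared and 6497 probes changed. Pairing was not borne out: 2 of 7 pairs correlated over 0.1, the mean was 0.036, and 1 arsenic array correlated best with its own number; by file names it was 3 of 9 pairs, a mean of 0.048 and 1 array.

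Of values for single genes, 1530 kept direction and call, 31 lost the call, 80 moved and 20 changed sign. Under spike-in scaling the sign changed for hemoglobin beta chain (0.0076), POL (0.037), Fbxw9 (0.049), kinesin 21B (0.074), cytochrome c oxidase polypeptide II (0.64) and polyadenylate-binding protein 1 (0.26). Within slide 2 it changed for kinesin 21B (0.54) and apolipoprotein E (−0.073), and within slide 5 for alpha-1-antitrypsin (−0.25) and the delta-5 delta-6 desaturase (−0.13). Other probes had the opposite sign for 40S ribosomal protein S11 (−0.74), long-chain acyl-CoA dehydrogenase (−0.013), apolipoprotein A-I (−0.12), complement C3-1 (−0.35) and factor H (−0.53), cytochrome c oxidase polypeptide II (0.14), liver fatty acid-binding protein (−1.72), POL (2.86) and troponin C (−0.44 and −0.38). The median of a list against all named genes changed sign for the complement list under quantile normalization (−0.00499) and no filter (−0.094), for chaperones (−0.20) and ribosomal proteins (0.0027) with no filter, for sarcomere (−0.11) and lipid genes (−0.41) with the mean of a gene's probes, and for ribosomal proteins against all probes (0.092). The cause was not tested. In the dimmest of 3 equal parts of the probes, where signal over background is lowest, 43% had another call than the main one under quantile normalization and 45% under normexp, more than in the other parts; whether background limits these calls was not isolated.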

Other observations

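Spike-in scaling, and the genes named in this part, were chosen after the values were seen.

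Smaller lists, with under 5 measured genes and no list test, held further changes. All 4 measured heart genes rose (4 adjusted over the list alone), with a median of 0.62, among them cardiac troponin T at 0.90, although all 4 also belong to the sarcomere list and 1 of them, troponin C, had other probes called lower (−0.44 and −0.38). Of the growth factor genes, insulin-like growth factor binding protein 5 rose by 1.996 and binding protein 7 by 0.91, while the type 1 insulin-like growth factor receptor, which carries the growth signal into the cell, fell by 1.08 but lay at 0.18 with no call under spike-in scaling, so 2 rose and 1 fell of 3. Glutamine synthetase, the only measured gene of the glia list and also a gene of liver and muscle, rose by 1.51. In the metal and oxidative stress list 2 of 3 rose, a glutathione S-transferase at 1.204 and mitochondrial thioredoxin at 0.81, while extracellular superoxide dismutase (0.07) did not pass.

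Among structural genes, collagen alpha 1 (−0.75) and laminin alpha 2 (−0.25) fell and fibrillin 2 (0.16) did not pass, but 1 of these 3 fell under quantile normalization and all 3 rose under spike-in scaling. The calcium handling genes of muscle, ryanodine receptor 2 (−0.18) and 2 calcium ATPases (−0.06 and 0.37), did not pass. Both lists were chosen knowing of the study's publication. Of 2 hemoglobin genes, the beta chain fell, though not under spike-in scaling, and the beta-B chain (0.38) did not pass. The egg coat protein zona pellucida sperm-binding protein 3 (−0.65) and the Wnt receptor frizzled 8 (−0.65) fell but rose under spike-in scaling, and median scaling and normexp ended both calls and quantile normalization that of frizzled 8. Inner centromere protein rose by 0.68, a call that quantile normalization and normexp ended. Each of these genes was the only measured gene of its list. The 2 disulfide isomerases of the endoplasmic reticulum stress list (0.57 and −0.35) did not pass. The lists for cartilage and bone, glucocorticoid targets, gut, ionocytes, lens, myogenic regulators, neurons, notochord and vessels, p53 targets and retina had 0 measured genes.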
